A study of Homo sapiens with 4 samples.

How the data were processed

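Total RNA of transfected H1299 cells was read on 4 two-colour Agilent 4x44K arrays, per the file headers all on 1 slide. Per the labels, the green dye Cy3 carried RNA of cells with wild-type p53 and the red dye Cy5 RNA of cells with p53 mutated at codon 175 on every array, with 3 hypoxic arrays as biological replicates and 1 normoxic array. No array had the dyes swapped. The deposited scanner files hold spot and local background brightness in intensity units, read by Feature Extraction 10.5.1.1 with the protocol GE2_105_Jan09 and coordinates of build hg18, per the file headers. Processed signals in the same files, also intensity, were background-subtracted and dye-normalized by that software, per the file headers, and a deposited log10 ratio of red over green goes with them. The deposited series matrix holds log2 values, which lay within 0.001 of the log2 ratio of the green over the red processed signal at the probes with 1 spot, and so are wild-type over mutant p53, not centred.

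The main values came from mean spot signals and the median local background. In R 4.3.3 with limma 3.58.1, signals were corrected with normexp and an offset of 50, and the ratios of each array were normalized by loess with weight 0 for control and outlier spots. On hypoxia array 1, 145 spots, 137 of them probes of genes, had a local background above 2 times the median of its channel. The cause of this was not examined. The values reached 56615 in green, where the median was 22, and 28274.5 in red, where it was 57. With these values the normexp mean was −747.9 in green and −571.6 in red, against −5.1 and −16.1 when those spots were given the median background. As given, the fit also shrank the ratios of dim probes on that array. The median absolute deviation of the ratios was taken over the dimmest 25% of the probes used for the tested genes. It was 0.012 as given and 0.180 after the repair, and 0.163 to 0.202 on the other arrays. The repair was therefore made, the spots were left out, and the values as given were kept as an alternative; this was decided after seeing the data. Outlier spots numbered 227, 144, 127 and 91 on hypoxia arrays 1 to 3 and the normoxic array.

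Spots of a probe were averaged, and of 41000 probes 40783 had a value on all arrays and 217 were left out. A probe was kept where it was well above background on all arrays of at least 1 of the 4 RNA groups, which 28696 were, and 24431 were so in both channels of all arrays. Probes were named through their RefSeq accession (24810 probes), by a current symbol in the file (2495), by a synonym of a single gene (780) or by the file's own name (1653), while 10647 had no gene name and 615 matched several genes. Each gene was represented by its brightest kept probe, which gave 14778 genes, 5631 of them with more than 1 kept probe.

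Wild-type over mutant ratios in each condition, and their difference, were tested with lmFit and eBayes on the log2 ratio of each array, with 1 coefficient per condition, so that the array pairs the 2 RNA samples. Hypoxia was compared with normoxia within each p53 form by the separate-channel method (Aquantile between arrays, then lmscFit with statmod 1.5.0) on all 8 channels, with an estimated within-spot correlation of 0.300. The single normoxic array was assumed in every test to vary like the hypoxic ones. P values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. A fold is given as at least a value where the dimmer group was not well above background, with that group's signal on each array set to its own value or to the lowest signal well above background there, whichever was higher. Comparisons, their tests, gene lists and most other choices of processing were written before the data were examined, while the background repair, 2 of those choices and 4 of 7 tests of explanations came after.

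The 17 gene lists were tested in each of the 5 comparisons, as counts of passing members, as counts adjusted over the list alone, and with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the 85 tests. With the preset correlation 46 of 85 passed, and with an estimated correlation 0 of 85. The estimate comes from 2 residual degrees of freedom, and the test then takes its reference from them too. Hardly any list could pass on so few, so a lost call does not show that correlated members account for it. The unfolded protein response and ATF4 list in the hypoxic ratio had an estimated correlation of −0.04, below the preset one, and still lost its call. Genes named in the text are the 8 with the largest rise and the 8 with the largest fall that passed with the same sign in each hypoxic array and were well above background in the brighter group; up to 4 members of each list with the smallest p; and 22 genes fixed whatever their values, among them CDKN1A, MDM2 and VEGFA. Some genes that these rules name are not reported here. Others were named after their values were seen: PPM1D and RPS27L in the report, and further interferon genes and 4 gene groups in the closing section.

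The alternatives were no background correction, an offset of 0, the processed signals, the series matrix, median centring, other scalings between arrays, no filter and a stricter filter, the mean over probes or every probe, eBayes with trend and robust settings, channels unpaired or fitted separately, and leaving out each hypoxic replicate. Averaging hypoxia arrays 1 and 2 was added after seeing the data, since their wild-type channels lay close together: over 214 probes printed on several spots, the spread of the difference between the 2 arrays was 0.059, against 0.051 from spot noise alone and 0.117 for the other pairs of hypoxic arrays. They are labelled as separate biological replicates and were kept so.

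Across all genes the log2 ratios of pairs of hypoxic arrays correlated at 0.815 to 0.859, and those of hypoxic with normoxic arrays at 0.732 to 0.760. The median SE of a log2 ratio was 0.051 in hypoxia, 0.088 in normoxia and 0.102 for their difference, and 0.085 for a change within a p53 form. The programs were tested on simulated data: 100% of 1.5-fold changes were found for the hypoxic ratio, with 0.08% of unchanged genes called, and 49.3% of 1.5-fold and 98.5% of 2-fold changes for the difference, with 0.06% of unchanged genes called. Within a p53 form 70.1% of 1.5-fold changes were found, with 0.23% of unchanged genes called. The simulated values were independent normal noise with the spread of the hypoxic arrays, also for the normoxic array. They held no dye effect, culture effect or correlation between genes, and background correction and loess were not part of the test. The shares of unchanged genes called therefore do not cover such effects in the real arrays. The package data.table (version 1.17.8) read the files, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.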

Results

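Gene expression was measured in H1299, an established human lung cancer cell line that lacks its own p53, after transfection with wild-type p53 or with p53 mutated at codon 175, in the DNA-binding domain of this tumour suppressor. The transfected cells were kept for 16 h in hypoxia, with under 0.1% oxygen, or in normoxia, with 21% oxygen. Total RNA was hybridised to 4 long-oligonucleotide arrays that each read 2 RNA samples on the same spots. Every array set 1 wild-type sample, in the green dye Cy3, against 1 mutant sample of the same oxygen condition, in the red dye Cy5. The hypoxic pair had 3 biological replicates per the labels and the normoxic pair had 1. Each array held 43376 spots for 41000 probes, the median spot brightness ranged from 125.6 to 140.7 in the green channel and from 154.6 to 171.3 in the red channel, and no gene spot was saturated. Between 67.7% and 71.9% of gene spots were well above background in the green channel, and between 62.5% and 69.0% in the red. A total of 14778 genes were tested, and values of genes and lists given without a unit are on the log2 scale. The number of arrays limits the precision, and a fold below rests on 3 hypoxic arrays and 1 normoxic array.

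The first comparison asked which transcripts differed between wild-type and mutant p53 in hypoxia. Of the tested p53 targets in the arrest and feedback, apoptosis and other lists, 14 of 17, 11 of 19 and 16 of 25 were higher with wild-type p53, and 17 of 26 G2/M genes and 16 of 27 ribosomal protein genes were lower. BTG2, an antiproliferative p53 target, was 5.48-fold higher (log2 ratio 2.45 ± 0.065 SE, n = 3 arrays, limma adjusted p = 1.02e-07). GDF15, a secreted stress cytokine, was 4.33-fold higher (2.11 ± 0.068 SE), AREG, a ligand of the epidermal growth factor receptor, 4.32-fold (2.11 ± 0.059 SE), and FDXR, the mitochondrial ferredoxin reductase, 3.64-fold (1.86 ± 0.050 SE). CYFIP2, a regulator of the actin cytoskeleton, was 2.73-fold higher, SRSF6, a splicing factor, 2.56-fold, and VWCE 2.41-fold. The other probe of CYFIP2 had a log2 ratio of 0.47 and that of SRSF6 0.34.

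Of the 17 tested arrest and feedback targets of p53, 14 were higher and 0 lower, also adjusted over the list alone, with a median log2 ratio of 0.62 (camera adjusted p = 5.08e-07; adjusted p = 0.459 with an estimated correlation). Besides BTG2 and GDF15, the kinase gene PLK3 had a log2 ratio of 1.03, the phosphatase gene PTP4A1 0.83 (other probes −0.29 and 0.58), MDM2, the ubiquitin ligase that degrades p53, 1.19, and CDKN1A, the cyclin-dependent kinase inhibitor p21, 0.47 ± 0.049 SE (adjusted p = 7.04e-05), with 1.39 on its other probe. Of the 19 apoptosis targets, 11 were higher and 6 lower, also adjusted over the list alone (median 0.25, camera adjusted p = 0.0287; adjusted p = 0.568 with an estimated correlation), a call lost under 6 alternatives, such as the processed signals (adjusted p = 0.0738). AEN, an apoptosis-enhancing nuclease, had a log2 ratio of 1.02, the BH3-only gene PMAIP1 0.76, the death receptor gene FAS 0.70 and TP53I3 0.53, all higher. PHLDA3, an inhibitor of Akt signalling, was at least 2.11-fold higher, a bound because its mutant samples were not well above background. BBC3, which encodes the BH3-only protein PUMA, was lower on its brightest probe (−0.34 ± 0.112 SE, adjusted p = 0.0292), while its other 2 probes had log2 ratios of 1.00 and 0.82, and the mean over its probes was 0.49 (adjusted p = 0.000386). Of the 25 targets in repair, metabolism and other functions, 16 were higher and 3 lower, also adjusted over the list alone (median 0.46, camera adjusted p = 7.3e-05; adjusted p = 0.459 with an estimated correlation), among them FDXR, CYFIP2, the nucleotide excision repair gene DDB2 (1.08) and the translesion polymerase gene POLH (0.85).

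The 6 hypoxia-inducible p53 genes that the study itself named were all higher, also adjusted over the list alone (median 1.13, camera adjusted p = 8.67e-06; adjusted p = 0.459 with an estimated correlation). Because the study chose these genes on its own samples, and because BTG2, CYFIP2, PHLDA3 and SULF2 also stand in the other p53 lists, that count is not independent evidence. INPP5D, a lipid phosphatase gene, was at least 2.2-fold higher and SULF2, an extracellular sulfatase gene, at least 1.55-fold, since neither was well above background in the mutant samples. KANK3 had a log2 ratio of 0.42 ± 0.050 SE (adjusted p = 0.00015).

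Of 26 G2/M genes, 17 were lower and 3 higher with wild-type p53 in hypoxia, also adjusted over the list alone (median −0.20, camera adjusted p = 0.000778; adjusted p = 0.568 with an estimated correlation), with log2 ratios of −0.66 for cyclin B1 (CCNB1), −0.59 for the spindle checkpoint kinase gene BUB1B, −0.46 for PRC1 and −0.37 for AURKA. Of 26 G1/S and replication genes, 15 were lower and 3 higher, also adjusted over the list alone (median −0.23, camera adjusted p = 0.00474; adjusted p = 0.673 with an estimated correlation): the replicative helicase genes MCM4 and MCM7 were at −0.51 and −0.48, SLBP at −0.40 and MCM2 at −0.42, and the uracil glycosylase gene UNG was higher (0.61). Ribosomal protein genes were lower in 16 and higher in 4 of 27, also adjusted over the list alone (median −0.16, camera adjusted p = 0.00109; adjusted p = 0.459 with an estimated correlation). RPLP0 was at −0.85, RPL30 at −0.62, RPL3 at −0.62 and RPS2 at −0.58. Oxidative phosphorylation genes were lower in 12 and higher in 3 of 25, and in 12 and 4 adjusted over the list alone (median −0.11, camera adjusted p = 0.0282; adjusted p = 0.459 with an estimated correlation). ATP5F1A was at −0.44 and UQCRC1 at −0.42, and SDHC higher (0.63). The ribosomal list was no longer called with the scanner software's processed signals (median −0.11, adjusted p = 0.253), nor was the oxidative phosphorylation list (−0.10, adjusted p = 0.151). The unfolded protein response and ATF4 genes were higher in 13 and lower in 3 of 23, also adjusted over the list alone (median 0.27, camera adjusted p = 0.00289; adjusted p = 0.459 with an estimated correlation). The eIF2α phosphatase subunit gene PPP1R15A was at 0.72, the endoplasmic reticulum chaperone gene HSPA5 at 0.61 (other probe 0.06), ATF3 at 0.57 and PDIA4 at 0.52. With median centring that list had a median of 0.04 and no call (adjusted p = 0.307).

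The other lists had no camera call in hypoxia with the chosen processing, and 2 of them were near the threshold. HIF-target glycolysis genes were lower in 12 and higher in 4 of 21, also adjusted over the list alone (median −0.16, camera adjusted p = 0.0609), and the list was called lower under 4 other choices of processing or arrays, such as median centring (adjusted p = 0.00104). PGAM1 was at −0.48 and HK2 at 0.40. The other HIF targets were lower in 12 and higher in 7 of 30, or 8 adjusted over the list alone (median −0.07, camera adjusted p = 0.461); the histone demethylase gene KDM3A was lower (−0.45). VEGFA, the vascular growth factor gene, was higher on its brightest probe (0.39, adjusted p = 0.000338), and its other 3 probes had log2 ratios of 0.11, −0.17 and 0.06. NDRG1 (0.07, adjusted p = 0.262), the glucose transporter gene SLC2A1 (0.03, adjusted p = 0.635) and DDIT3 (0.04, adjusted p = 0.504) did not pass. DNA repair genes were higher in 4 and lower in 3 of 17, and in 3 and 2 adjusted over the list alone (median −0.06, camera adjusted p = 0.653). Cholesterol synthesis genes were higher in 5 and lower in 7 of 19, or 8 lower adjusted over the list alone (median −0.07, camera adjusted p = 0.459). SQLE was at 0.58 and DHCR7 at −0.46. Interferon response genes were higher in 6 and lower in 6 of 18, also adjusted over the list alone (camera adjusted p = 0.687), with a median of 0.01 and a mean of −0.03 on opposite sides of 0; RIGI, a cytosolic RNA sensor gene, was higher (0.69) and ISG15 lower (−0.61). NF-kB and inflammatory genes were higher in 7 and lower in 2 of 12, or 3 lower adjusted over the list alone (median 0.14, camera adjusted p = 0.228). The chemokine gene CXCL1 was at 0.94. Heat shock genes were higher in 7 and lower in 2 of 10, also adjusted over the list alone (median 0.30, camera adjusted p = 0.0558), and the list was called higher under 7 other choices, such as no filter (adjusted p = 0.0224). HSPH1 was at 1.01 and HSPB1 at −0.50. Of 6 tested markers of other cell types, 1 was higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.916).

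The lower genes with the largest differences in hypoxia were ADAMTS7, a metalloprotease gene (−1.07 ± 0.098 SE, adjusted p = 4.22e-05), MAGED1 (−0.96), the transcription factor gene RUNX1 (−0.92), RPS26 (−0.92), COX1 (−0.91), ZNF791 (−0.90), the mitochondrially encoded CYTB (−0.87) and RPLP0. The file places the COX1 probe on chromosome 1. The other probes of RUNX1 had log2 ratios of 0.01 and −0.06, that of RPS26 −0.18 and that of ZNF791 −0.29. In all, limma called 7955 of 14778 genes, 4129 higher and 3826 lower (51.9% higher), of which 22 and 4 differed by at least 2-fold. With each array only centred on its median the higher share was 65.0%. The dyes were not swapped, so a dye effect of a probe's sequence cannot be told from the p53 form in the ratios here. Among 3230 called genes with another probe, the ratios of the pair of probes correlated across genes at 0.305 (95% interval 0.273 to 0.336) and had the same sign in 62.0%.

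**Figure D1:**
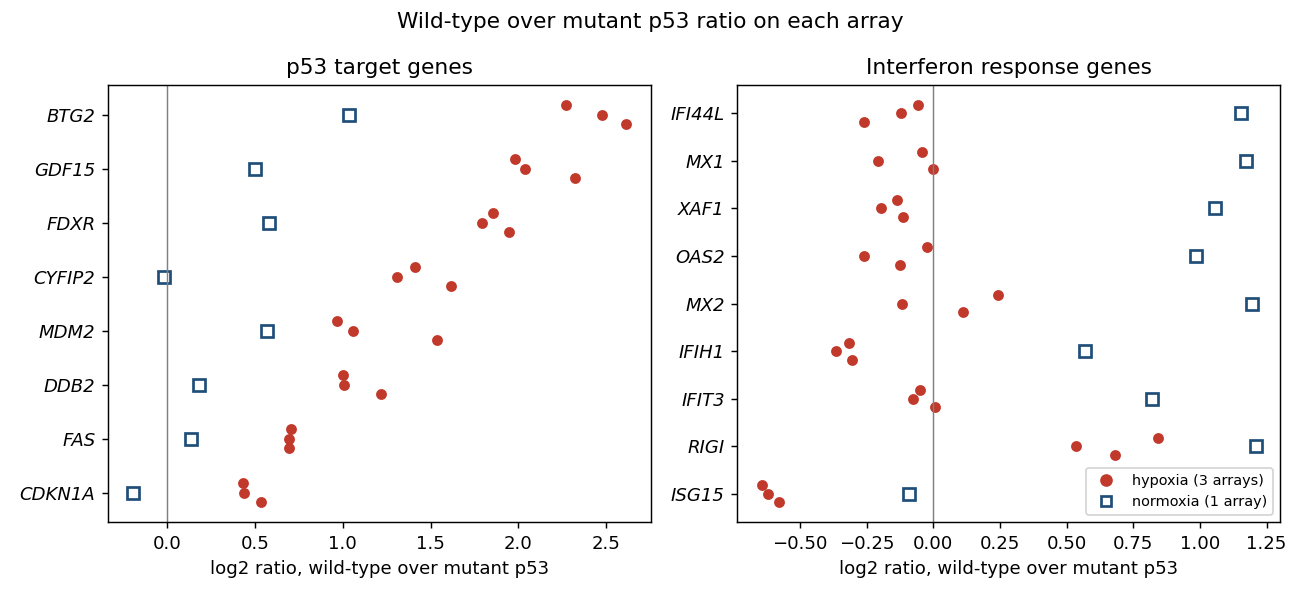
Log2 ratio of wild-type over mutant p53 (horizontal axis) for 8 target genes of p53 on the left and 9 interferon response genes on the right; each filled circle is 1 of the 3 hypoxic arrays and each open square the single normoxic array. For CYFIP2 the hypoxic arrays lie above the normoxic one, at −0.02, while for IFI44L the normoxic array, at 1.16, lies above the hypoxic ones.

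In normoxia the same ratio was read on the single normoxic array, whose spread was assumed to be that of the hypoxic arrays. Genes of the antiviral interferon response were among those with the largest differences: GBP1, an interferon-induced GTPase gene, was 2.59-fold higher (1.37 ± 0.103 SE), RSAD2, which encodes viperin, 2.58-fold (1.37 ± 0.110 SE), SAMD9 2.39-fold, SAMD9L 2.33-fold and RIGI 2.31-fold, with ZNF609 at 2.65-fold and SRSF6 at 2.31-fold. The other probes of these last genes had log2 ratios of 0.02 for ZNF609 and 0.34 for SRSF6. Of 18 interferon response genes, 14 were higher and 0 lower, and 15 were higher adjusted over the list alone (median 0.74, camera adjusted p = 5.16e-09; adjusted p = 0.459 with an estimated correlation); MX1 and IFI44L had log2 ratios of 1.17 and 1.16 and IFIT3 0.82.

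Fewer p53 targets passed in normoxia. Of the arrest and feedback targets 8 of 17 were higher and 0 lower, also adjusted over the list alone (median 0.25, camera adjusted p = 0.000757; adjusted p = 0.459 with an estimated correlation). BTG2 was at 1.04 ± 0.113 SE, PTP4A1 at 0.95 (other probes −0.42 and 0.35), the growth arrest gene GADD45A at 0.84, MDM2 at 0.57 and GDF15 at 0.50. CDKN1A did not pass on its brightest probe (−0.19 ± 0.084 SE, adjusted p = 0.114), and its other probe had a log2 ratio of 0.56. Of the apoptosis targets 5 were higher and 3 lower of 19, also adjusted over the list alone (median 0.04, camera adjusted p = 0.722): PMAIP1 was at 0.96 and AEN at 0.45, and BAX, a pore-forming protein gene of the mitochondrial membrane, and NINJ1 were lower (−0.51 and −0.54). The other BAX probes had log2 ratios of −0.16 and −0.06. FAS (0.14), TP53I3 (−0.13) and BBC3 (−0.41 on its brightest probe) did not pass. The other probes of BBC3 had log2 ratios of 0.67 and 0.72. Of the targets in repair, metabolism and other functions 6 of 25 were higher and 0 lower, also adjusted over the list alone (median 0.11, camera adjusted p = 0.232). FDXR was at 0.58 and TIGAR, a regulator of glycolysis, at 0.45. Of the study's own 6 genes 3 were higher, and 4 adjusted over the list alone, which is not independent evidence (median 0.40, camera adjusted p = 0.0122; adjusted p = 0.47 with an estimated correlation), a call lost with the stricter filter (adjusted p = 0.187). PHLDA3 was at least 1.31-fold and SULF2 at least 1.14-fold higher, while INPP5D (adjusted p = 0.0593), KANK3 (0.17) and CYFIP2 (−0.02, adjusted p = 0.932) did not pass.

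G2/M genes were lower in 10 and higher in 2 of 26 in normoxia, and 12 were lower adjusted over the list alone (median −0.20, camera adjusted p = 0.00182; adjusted p = 0.599 with an estimated correlation). CCNB1 was at −0.59 and AURKA at −0.49. Ribosomal protein genes were lower in 12 and higher in 0 of 27, and 14 were lower adjusted over the list alone (median −0.24, camera adjusted p = 2.12e-05; adjusted p = 0.459 with an estimated correlation). RPLP0 was at −0.98; the call was lost with the processed signals (median −0.12, adjusted p = 0.0871). The unfolded protein response and ATF4 genes were higher in 12 and lower in 1 of 23, or 2 lower adjusted over the list alone (median 0.28, camera adjusted p = 0.000396; adjusted p = 0.459 with an estimated correlation). HSPA5 was at 0.97, PDIA4 at 0.89 and ATF3 at 0.59. DNA repair genes were higher in 4 and lower in 0 of 17, also adjusted over the list alone (median 0.15, camera adjusted p = 0.0281; adjusted p = 0.568 with an estimated correlation).

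The remaining lists had no camera call in normoxia with the chosen processing. Of 26 G1/S genes 4 were higher and 0 lower, and 3 were higher adjusted over the list alone (camera adjusted p = 0.444). UNG was at 0.81 and cyclin E2 (CCNE2) at 0.56. HIF-target glycolysis genes were higher in 3 and lower in 3 of 21, or 5 and 6 adjusted over the list alone (camera adjusted p = 0.722), and the other HIF targets were higher in 4 and lower in 4 of 30, also adjusted over the list alone (camera adjusted p = 0.755). HK2 was at 0.76. Cholesterol synthesis genes were higher in 6 and lower in 5 of 19, or 7 and 6 adjusted over the list alone, with a median of −0.13, a mean of 0.03 and a downward camera statistic (adjusted p = 0.926); HMGCS1 was at 0.78, and LSS at 0.41 on its brightest probe and −0.03 as the mean over its probes. Oxidative phosphorylation genes were lower in 6 and higher in 2 of 25, also adjusted over the list alone (camera adjusted p = 0.0756, but 0.00407 with median centring and 0.00802 with the mean over probes), with cytochrome c (CYCS) at 0.79 on its brightest probe and 0.29, −0.56 and −0.37 on the others. NF-kB and inflammatory genes were higher in 2 and lower in 2 of 12, or 3 higher adjusted over the list alone (camera adjusted p = 0.687), and heat shock genes were higher in 3 and lower in 1 of 10, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.767). None of the 6 markers of other cell types passed, also adjusted over the list alone (camera adjusted p = 0.722).

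The lower genes with the largest differences in normoxia were ADAMTS7 (−1.05 ± 0.170 SE, adjusted p = 0.00304), the histone genes H4C2 (−1.0) and H4C13 (−0.98), RPLP0, the carboxypeptidase gene CPM (−0.94, other probe −0.34), NDUFB11 of respiratory complex I (−0.91) and RPL6 (−0.88, other probe −0.34). The test called 4233 genes, 2345 higher and 1888 lower (55.4% higher, and 69.8% with median centring), of which 27 and 4 differed by at least 2-fold. The scanner software's processed signals gave 1447 calls and normexp with an offset of 0 gave 2113. As in hypoxia the dyes cannot be told from the p53 form, and the pairs of probes of 1757 called genes correlated at 0.411 and had the same sign in 68.4%.

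The next comparison tested whether the wild-type over mutant ratio itself differed between hypoxia and normoxia, a difference in which a dye effect common to all arrays cancels. It was larger in hypoxia for 13 of 61 p53 targets and smaller for 11 of 18 interferon response genes. The ratio of GDF15 was 3.06 times as large in hypoxia (log2 difference 1.61 ± 0.135 SE, adjusted p = 0.00159), that of CYFIP2 2.75 times (1.46 ± 0.124 SE, 0.54 on its other probe), of BTG2 2.67 times (1.41 ± 0.131 SE), of RRAD, a Ras-related GTPase gene, 2.46 times (1.30 ± 0.112 SE) and of FDXR 2.44 times (1.29 ± 0.101 SE). The smooth muscle actin gene ACTA2 (1.17) and AREG (1.14) followed. At the other end were IFI44L (−1.30 ± 0.108 SE), the antiviral GTPase genes MX1 (−1.26 ± 0.109 SE) and MX2 (−1.11, other probe −0.49), XAF1 (−1.21 ± 0.095 SE), the oligoadenylate synthetase gene OAS2 (−1.12), the DNA sensor gene IFI16 (−0.95) and SAMD9 (−0.95).

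Of the arrest and feedback targets 5 of 17 had a larger ratio in hypoxia and 0 a smaller one, or 9 and 1 adjusted over the list alone (median 0.27, camera adjusted p = 4.24e-06; adjusted p = 0.459 with an estimated correlation). The 5 that passed over all genes were GDF15, BTG2, PLK3 (0.67), CDKN1A (0.66 ± 0.097 SE, adjusted p = 0.0227) and PPM1D, a phosphatase gene (0.60). MDM2 did not pass (0.62 ± 0.189 SE, adjusted p = 0.198). Of the apoptosis targets 3 of 19 had a larger ratio, PIDD1 (0.78), FAS (0.56) and PHLDA3, or 6 and 1 smaller adjusted over the list alone (median 0.15, camera adjusted p = 0.000122; adjusted p = 0.459 with an estimated correlation), and TP53I3 (0.66, adjusted p = 0.0509) and BBC3 (0.07, adjusted p = 0.912) did not pass. Of the targets in repair, metabolism and other functions 5 of 25 had a larger ratio, FDXR, CYFIP2, DDB2 (0.89), POLH (0.71) and the ribosomal-like protein gene RPS27L (0.57), or 10 and 1 smaller adjusted over the list alone (median 0.25, camera adjusted p = 3.66e-09; adjusted p = 0.459 with an estimated correlation). PPM1D and RPS27L were named after their values were seen. For BBC3, the value of 0.07 is that of its brightest probe, and its other probes were at 0.32 and 0.10. Of the study's 6 genes 3 passed, and 6 adjusted over the list alone, which is not independent evidence (median 0.73, camera adjusted p = 4.48e-10; adjusted p = 0.459 with an estimated correlation). INPP5D, SULF2 and KANK3 (0.25, adjusted p = 0.315) did not pass over all genes. For PHLDA3, INPP5D and SULF2 no size is given, since the mutant samples were not well above background in either condition, and their calls and the list's median rest on such signals.

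Of the 18 interferon response genes 11 had a smaller ratio in hypoxia and 0 a larger one, and 16 a smaller one adjusted over the list alone (median −0.67, camera adjusted p = 4.86e-23; adjusted p = 0.459 with an estimated correlation), IFIH1 (−0.90) and IFIT3 (−0.86) among them. No member passed over all genes in 4 further lists that camera called. The G1/S list had a median difference of −0.25, with 5 genes smaller adjusted over the list alone (camera adjusted p = 4.3e-09; adjusted p = 0.459 with an estimated correlation) and CCNE2 at −0.46. The DNA repair list had a median of −0.22, with 0 genes adjusted over the list alone (camera adjusted p = 4.92e-05; adjusted p = 0.459 with an estimated correlation). The HIF-target glycolysis list had a median of −0.06, with 0 genes adjusted over the list alone (camera adjusted p = 0.029; adjusted p = 0.6 with an estimated correlation) and SLC2A1 at −0.21. Its call was lost under 6 other choices of processing or arrays, such as the processed signals (adjusted p = 0.238). The heat shock list had a median of 0.16, with 2 genes larger adjusted over the list alone (camera adjusted p = 0.0282; adjusted p = 0.649 with an estimated correlation) and HSPA8 at 0.73 (adjusted p = 0.12), and its call was lost under 4 other choices of processing, such as the processed signals (adjusted p = 0.366).

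In the lists without a camera call, 1 of 12 NF-kB and inflammatory genes had a larger ratio in hypoxia, CXCL1 (0.67, adjusted p = 0.033), or 2 adjusted over the list alone (camera adjusted p = 0.152). No gene passed among 26 G2/M genes (camera adjusted p = 0.936), 30 other HIF targets (0.0557), 23 unfolded protein response and ATF4 genes (0.125), 25 oxidative phosphorylation genes (0.685), 27 ribosomal protein genes (0.187) or 6 markers of other cell types (0.66), and 0 passed in these adjusted over the list alone. The other HIF targets were called smaller under 6 other choices of processing or arrays, such as the processed signals (adjusted p = 0.0415), and with median centring the unfolded protein response (0.00121) and ribosomal (0.0373) lists were called. Among 19 cholesterol synthesis genes 0 passed, or 1, with a smaller ratio, adjusted over the list alone (camera adjusted p = 0.208). The differences for VEGFA (0.29), NDRG1 (0.17), DDIT3 (0.10), ATF3 (−0.02), CCNB1 (−0.07) and MCM2 (−0.25) did not pass.

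In total limma called 84 genes, 29 with a larger and 55 with a smaller ratio in hypoxia, while 2110 had an unadjusted p under 0.05. Of the 29, 13 were in the p53 target lists, and of the 55, 11 were in the interferon list. Among 35 called genes with another probe, 34 pairs had the same sign and correlated at 0.892. The count rests on 1 normoxic array and on single replicates: it was 11 without hypoxia replicate 3, where 72.7% were larger, 167 without replicate 2, and 364 with replicates 1 and 2 averaged, a setting chosen after seeing the data. With the scanner software's processed signals limma called 0 genes, with 1547 at an unadjusted p under 0.05, and with an offset of 0 it called 1.

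The effect of hypoxia was then measured within each p53 form, where both sides carried the same dye. With wild-type p53, most tested targets of the hypoxia-inducible factor HIF, all genes of the unfolded protein response and ATF4 list and 13 of 17 arrest and feedback targets of p53 rose in hypoxia, and most cell-cycle, replication and repair genes fell. PFKFB4, a regulator of glycolysis, rose 19.8-fold (log2 change 4.31 ± 0.105 SE, adjusted p = 2.52e-08), ANKRD37 15.1-fold (3.92 ± 0.088 SE), NDRG1, a stress-induced differentiation gene, 12.1-fold (3.59 ± 0.099 SE, other probe 0.32), the chemokine receptor gene CXCR4 9.82-fold (3.30 ± 0.087 SE), HSPA5 9.47-fold (3.24 ± 0.081 SE), the mitophagy gene BNIP3 8.62-fold and HERPUD1, a component of endoplasmic-reticulum-associated degradation, 8.62-fold. The non-coding SNHG12 rose 7.68-fold. The complement inhibitor gene CD59 fell 6.55-fold (−2.71 ± 0.075 SE), DGAT2, which makes triglyceride, 6.25-fold (−2.64 ± 0.085 SE), the osteopontin gene SPP1 6.04-fold, DEPP1 5.38-fold, E2F2 4.86-fold (log2 change 0.29 on its other probe), HPDL 4.78-fold, the transcription regulator gene ID1 4.70-fold and the hormone gene CRH 4.66-fold.

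Of the 21 HIF-target glycolysis genes 17 rose and 0 fell with wild-type p53, also adjusted over the list alone (median 0.73, camera adjusted p = 3.34e-09; adjusted p = 0.459 with an estimated correlation). HK2 was at 2.86, SLC2A3 at 2.70, SLC2A1 at 1.81 and LDHA at 1.78. Of 30 other HIF targets 27 rose and 1 fell, or 2 fell adjusted over the list alone (median 1.78, camera adjusted p = 1.64e-14; adjusted p = 0.459 with an estimated correlation). VEGFA was at 2.85 ± 0.119 SE. CA9, a carbonic anhydrase gene of the HIF list, was not well above background in any RNA group and was not tested. All 23 unfolded protein response and ATF4 genes rose, also adjusted over the list alone (median 1.46, camera adjusted p = 6.61e-16; adjusted p = 0.388 with an estimated correlation). DDIT3 was at 2.82, PDIA4 at 2.41 and ATF3 at 2.03. Of the arrest and feedback targets of p53, 13 of 17 rose and 0 fell, also adjusted over the list alone (median 0.63, camera adjusted p = 8.5e-06; adjusted p = 0.459 with an estimated correlation). GDF15 was at 2.42 ± 0.112 SE, the sestrin gene SESN2 at 2.33, BTG2 at 1.53, GADD45A at 1.38, MDM2 at 0.63 (other probe −0.05) and CDKN1A at 0.39. Of the targets in repair, metabolism and other functions 17 of 25 rose and 1 fell, or 2 fell adjusted over the list alone (median 0.35, camera adjusted p = 0.000683; adjusted p = 0.459 with an estimated correlation). CYFIP2 was at 1.29 and FDXR at 1.11. All 6 of the study's genes rose, also adjusted over the list alone, which is not independent evidence (median 0.85, camera adjusted p = 0.000273; adjusted p = 0.459 with an estimated correlation). INPP5D was at 0.95, PHLDA3 at 0.75, KANK3 at 0.72 and SULF2 at 0.37. Of the apoptosis targets 8 rose and 4 fell of 19, also adjusted over the list alone (median 0.13, camera adjusted p = 0.352). The death receptor gene TNFRSF10B was at 1.02 and TP53I3 at 0.32, while BBC3 (0.21 on its brightest probe) and FAS (0.11) did not pass. The other probes of BBC3 were at 1.25 and 0.83.

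All 26 G2/M genes fell with wild-type p53, also adjusted over the list alone (median −1.17, camera adjusted p = 8.28e-14; adjusted p = 0.459 with an estimated correlation). TOP2A was at −1.95, CDK1 at −1.88 and CCNB1 at −1.17. Of 26 G1/S and replication genes 25 fell, also adjusted over the list alone (median −1.15, camera adjusted p = 4.17e-13; adjusted p = 0.459 with an estimated correlation). The ribonucleotide reductase gene RRM2 was at −2.11, PRIM1 at −1.52 and MCM2 at −1.37. Of 17 DNA repair genes 15 fell and 0 rose, also adjusted over the list alone (median −0.77, camera adjusted p = 2.68e-06; adjusted p = 0.459 with an estimated correlation). BARD1 was at −1.42 and FANCA at −1.25. All 10 heat shock genes fell, also adjusted over the list alone (median −0.60, camera adjusted p = 0.00201; adjusted p = 0.615 with an estimated correlation). DNAJA1 was at −0.86 and HSPE1 at −0.80. Of 25 oxidative phosphorylation genes 18 fell and 0 rose, and 20 fell adjusted over the list alone (median −0.28, camera adjusted p = 0.000307; adjusted p = 0.459 with an estimated correlation). Of 18 interferon response genes 12 fell and 3 rose, or 13 fell adjusted over the list alone (median −0.41, camera adjusted p = 0.0251; adjusted p = 0.719 with an estimated correlation). IFI44 was at −1.10 and IRF7, which rose, at 0.53. That list's call was lost with the processed signals (adjusted p = 0.053).

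Cholesterol synthesis genes rose in 5 and fell in 8 of 19, or 6 rose adjusted over the list alone (camera adjusted p = 0.66). STARD4 was at 1.11. Ribosomal protein genes rose in 4 and fell in 0 of 27, or 2 rose adjusted over the list alone (camera adjusted p = 0.176, but 0.0494 with the mean over probes), and NF-kB and inflammatory genes rose in 4 and fell in 2 of 12, also adjusted over the list alone (camera adjusted p = 0.653). TNFAIP3 was at 1.26 and the chemokine gene CCL2 at −1.26. Of 6 markers of other cell types 1 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.653). The separate-channel test called 7710 genes, 3750 higher and 3960 lower in hypoxia, of which 365 and 339 differed by at least 2-fold. The normoxic side is 1 sample, and the pairs of probes of 3065 called genes correlated at 0.804, with the same sign in 88.7%.

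**Figure D2:**
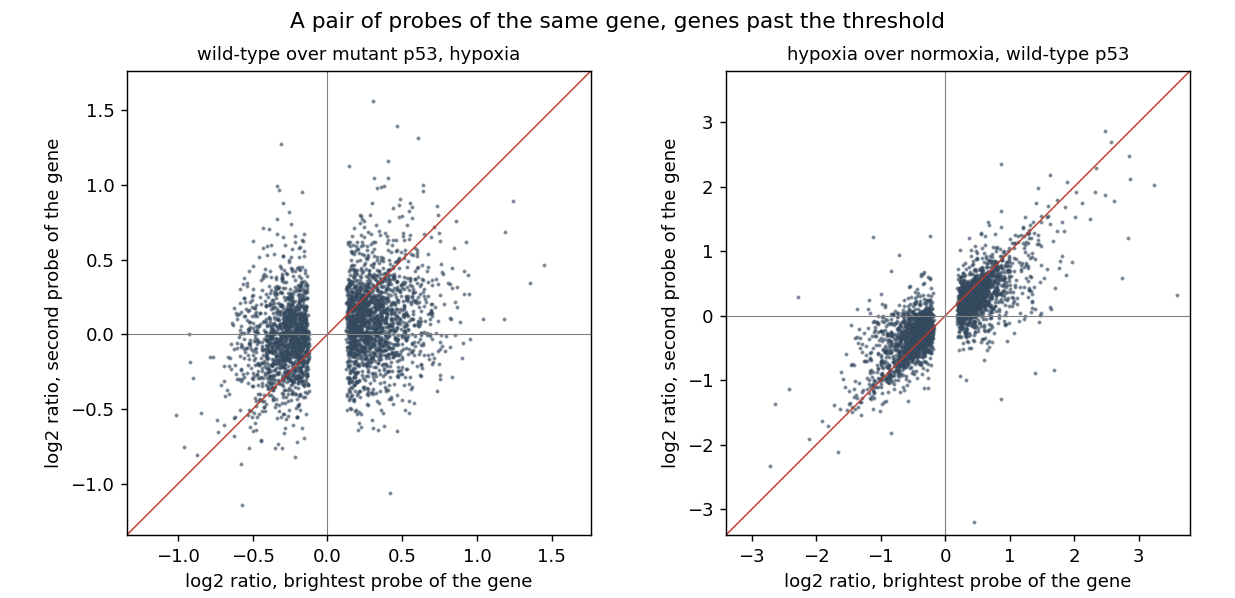
Log2 ratio of the brightest probe of each called gene (horizontal axis) against that of another probe of the same gene (vertical axis), 1 point per gene, for wild-type over mutant p53 in hypoxia on the left and hypoxia over normoxia with wild-type p53 on the right; the diagonal marks equal ratios. The correlation was 0.305 over 3230 genes on the left and 0.804 over 3065 genes on the right, and the gap around 0 on the horizontal axes comes from plotting called genes.

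With mutant p53, most tested HIF targets, 22 of 23 genes of the unfolded protein response and ATF4 list and 8 of 17 arrest and feedback targets of p53 rose in hypoxia, and most cell-cycle, replication and repair genes fell. PFKFB4 rose 19.2-fold (4.27 ± 0.105 SE, adjusted p = 2.29e-08), HSPA5 12.1-fold (3.60 ± 0.081 SE), ANKRD37 11.98-fold (3.58 ± 0.088 SE), NDRG1 10.8-fold (log2 change 0.33 on its other probe), the cadherin gene CDH15 9.70-fold (3.28 ± 0.163 SE), the hexokinase gene HK2 9.30-fold, CXCR4 8.90-fold and HERPUD1 8.73-fold. DGAT2 fell 6.49-fold (−2.70 ± 0.085 SE), CD59 6.34-fold, SPP1 5.84-fold, ID1 5.00-fold, CRH 4.90-fold, DEPP1 4.59-fold, HPDL 4.35-fold and CDK1 3.78-fold.

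Of the arrest and feedback targets of p53, 8 of 17 rose and 1 fell with mutant p53, or 9 rose adjusted over the list alone (median 0.29, camera adjusted p = 0.00608; adjusted p = 0.459 with an estimated correlation). SESN2 was at 2.27, GADD45A at 1.60, GDF15 at 0.81 ± 0.112 SE and PLK2 at 0.63, and CDKN1A fell by 0.27 ± 0.073 SE on the log2 scale (adjusted p = 0.0111). BTG2 (0.12, adjusted p = 0.389) and MDM2 (0.01, adjusted p = 0.951) did not pass. Of the apoptosis targets 2 rose and 8 fell of 19, also adjusted over the list alone (median −0.13, camera adjusted p = 0.371). TNFRSF10B was at 0.91, BID at −0.66, FAS at −0.46 and TP53I3 at −0.34. Of the targets in repair, metabolism and other functions 5 rose and 3 fell of 25, or 3 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.962), with a median of −0.05 and a mean of 0.01 on opposite sides of 0. Of the study's 6 genes 1 rose, also adjusted over the list alone, which is not independent evidence: KANK3 was at 0.47, and CYFIP2 was at −0.17 (adjusted p = 0.199; list median 0.09, camera adjusted p = 0.489). PHLDA3, INPP5D and SULF2 were not well above background in either mutant group.

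Of the HIF-target glycolysis genes 18 of 21 rose and 0 fell with mutant p53, also adjusted over the list alone (median 1.01, camera adjusted p = 7.28e-11; adjusted p = 0.459 with an estimated correlation). PDK1, the inhibitor of pyruvate dehydrogenase, was at 2.77, SLC2A3 at 2.66 and SLC2A1 at 2.02. Of 30 other HIF targets 27 rose and 1 fell, also adjusted over the list alone (median 1.89, camera adjusted p = 3.12e-16; adjusted p = 0.459 with an estimated correlation). BNIP3 was at 2.96 and VEGFA at 2.56. Of 23 unfolded protein response and ATF4 genes 22 rose, and 23 adjusted over the list alone (median 1.53, camera adjusted p = 7.14e-17; adjusted p = 0.388 with an estimated correlation). PDIA4 was at 2.78, DDIT3 at 2.72 and ATF3 at 2.05. All 26 G2/M genes fell, also adjusted over the list alone (median −1.12, camera adjusted p = 5.59e-15; adjusted p = 0.459 with an estimated correlation). TOP2A was at −1.72, UBE2C at −1.47 and CCNB1 at −1.09. Of 26 G1/S and replication genes 25 fell, and 26 adjusted over the list alone (median −0.92, camera adjusted p = 4.17e-13; adjusted p = 0.388 with an estimated correlation). RRM2 was at −1.78, the clamp gene PCNA at −1.32 and MCM2 at −1.12. Of 17 DNA repair genes 13 fell and 0 rose, also adjusted over the list alone (median −0.56, camera adjusted p = 7.62e-05; adjusted p = 0.459 with an estimated correlation). BARD1 was at −1.23 and FANCA at −1.15. All 10 heat shock genes fell, also adjusted over the list alone (median −0.84, camera adjusted p = 1e-05; adjusted p = 0.459 with an estimated correlation). HSPA8 was at −1.30 and HSP90AA1 at −1.08. Of 25 oxidative phosphorylation genes 16 fell and 0 rose, also adjusted over the list alone (median −0.26, camera adjusted p = 0.00103; adjusted p = 0.459 with an estimated correlation). SDHC was at −0.81.

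Interferon response genes rose in 7 and fell in 1 of 18 with mutant p53, also adjusted over the list alone (median 0.36, camera adjusted p = 0.0867). CXCL10 was at 1.46, IRF7 at 1.25, IFI44L at 0.68 and IFNB1 at 0.54. Without hypoxia replicate 1 that list was called higher (median 0.43, adjusted p = 0.0244). Cholesterol synthesis genes rose in 6 and fell in 7 of 19, also adjusted over the list alone (camera adjusted p = 0.962), with a median of 0.04 and a mean of −0.01 on opposite sides of 0; STARD4 was at 1.32. Ribosomal protein genes rose in 3 and fell in 0 of 27, or 1 rose adjusted over the list alone (camera adjusted p = 0.536). NF-kB and inflammatory genes rose in 2 and fell in 2 of 12, or 1 fell adjusted over the list alone (camera adjusted p = 0.962), with a median of 0.04 and a mean of −0.04; CCL2 was at −1.68 and TNFAIP3 at 1.17. Of the 6 markers of other cell types 1 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.379). In all 7474 genes were called, 3636 higher and 3838 lower in hypoxia, of which 331 and 275 differed by at least 2-fold. Both comparisons within a p53 form share the normoxic array, and the difference between them is the one tested as the change of the ratio.

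**Figure D3:**
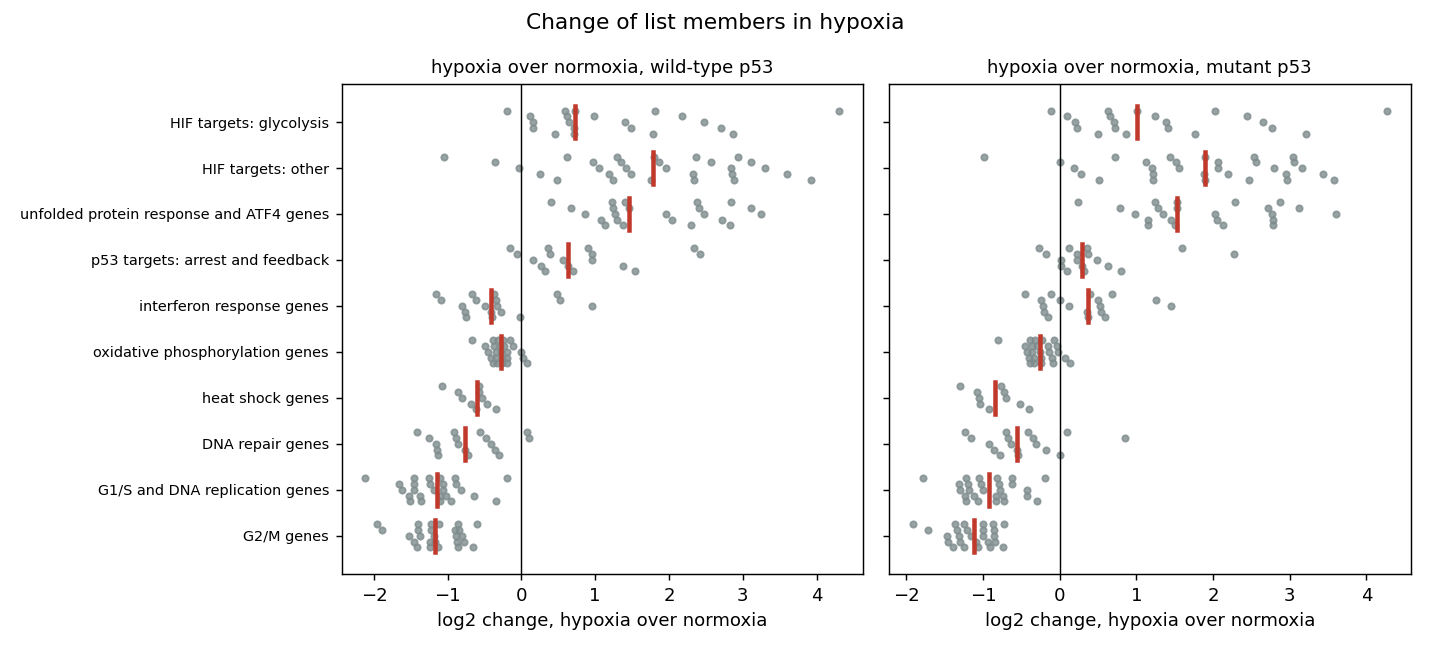
Log2 change in hypoxia over normoxia (horizontal axis) of the members of 10 gene lists, with wild-type p53 on the left and mutant p53 on the right; each grey point is a gene, spread vertically for legibility, and the red bar is the list's median. The G2/M list has a median of −1.17 on the left and −1.12 on the right, and the arrest and feedback targets of p53 a median of 0.63 and 0.29.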

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

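In this part the tests of probe pairs, base composition and sign assignments were written before their results were seen, and the other 4 tests after. All values listed here were picked out because the ratio of wild-type over mutant p53 differed between hypoxia and normoxia in the test of that difference, in 84 genes and 9 gene lists.

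The ratio was larger in hypoxia for GDF15 (1.612), CYFIP2 (1.461), BTG2 (1.415), RRAD (1.297), FDXR (1.285), ACTA2 (1.168), AREG (1.14), DDB2 (0.892), PIDD1 (0.783), POLH (0.709), PLK3 (0.672), CXCL1 (0.671), CDKN1A (0.661), PPM1D (0.601), RPS27L (0.573) and FAS (0.563). It was smaller for IFI44L (−1.302), MX1 (−1.256), XAF1 (−1.208), OAS2 (−1.121), MX2 (−1.114), IFI16 (−0.946), SAMD9 (−0.945), IFIH1 (−0.897) and IFIT3 (−0.861). Chosen after their values were seen were PPM1D, RPS27L and 7 further interferon-induced genes with a smaller ratio: OAS3 (−0.893), PLSCR1 (−0.866), DDX60L (−0.841), USP18 (−0.8), HERC5 (−0.797), IFITM1 (−0.762) and TAP1 (−0.593). The list medians of the difference were 0.268 for arrest and feedback targets of p53, 0.151 for apoptosis targets, 0.252 for targets in repair, metabolism and other functions, 0.735 for the study's own genes, −0.254 for G1/S genes, −0.058 for HIF-target glycolysis genes, −0.217 for DNA repair genes, −0.666 for interferon response genes and 0.159 for heat shock genes. All 9 list calls were lost with an estimated correlation, where the lowest camera adjusted p was 0.459. With 2 residual degrees of freedom that test passed 0 of 85, so it cannot tell whether correlation between members accounts for the loss.

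In hypoxia 7955 of 14778 genes differed between wild-type and mutant p53, and the dyes were never swapped. A dye effect of the probe sequence could be part of this: 2 probes of a gene correlated at only 0.305, and at 0.411 in the normoxic ratio. Both a dye effect and different transcript parts would lower the value, so by itself the test cannot tell. For hypoxia over normoxia, where the dye was the same, the pairs correlated at 0.804 with wild-type and 0.798 with mutant p53. Different transcript parts would lower those values too, but need not do so to the same extent, so this comparison cannot exclude them. More genes changed by at least 2-fold for hypoxia over normoxia, which can also raise a correlation, so a dye effect is not shown. Base counts of the probe accounted for 4.63% of the variance in a linear fit, too little for such a dye effect of base composition to be the main cause. They accounted for 8.3% in the normoxic ratio. For hypoxia over normoxia, where the dye was the same, the shares were 0.07% with wild-type and 0.03% with mutant p53. A smaller effect of base composition on the ratios thus stays open, and other features of the sequence were not tested. Turning the sign of any 1 array left 0 calls, but there are only 4 assignments, 1 of which is the real one, so a share under 0.05 cannot be had and chance is neither excluded nor shown. A dye-swapped array was not analysed here.

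Over the p53 targets together the median ratio was larger in hypoxia, and 13 of 61 passed. A dye effect common to all arrays cancels in the difference. The median difference over the 61 target genes was 0.225, with an SE of 0.061 from resampling these genes. The pattern weighed here is itself this difference, so the value restates it. It is not separate evidence against a dye effect. The SE treats genes that may change together as independent, and it holds no spread between arrays or cultures. The median ratio was 0.128 on the single normoxic array and 0.433, 0.387 and 0.443 on the hypoxic ones, so a normoxic culture that stood apart could give the same values and cannot be told from an effect of oxygen. Whether p53 itself differed between the conditions is not weighed here.

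Interferon response genes were higher with wild-type than with mutant p53 in normoxia, with a list median of 0.738, and not in hypoxia (−0.029, −0.041 and 0.022). A dye effect common to all arrays would alone give a median difference near 0. The median difference was −0.666, with an SE of 0.075 from resampling the 18 genes. Since the pattern was picked out by this same difference, the value restates it and is not separate evidence against a dye effect. That SE treats genes that may change together as independent and holds no spread between arrays or cultures. A response of the normoxic wild-type culture alone, for instance to the transfection, may be the cause: the list fell in the wild-type channel in hypoxia (−0.407) and its median in the mutant channel was 0.364, a value that did not pass and cannot tell. Of the 18 genes 12 fell and 3 rose in the wild-type channel, and 7 rose and 1 fell in the mutant channel. A change in the cells with mutant p53 can therefore also be part of the difference. With 1 normoxic array a response of a single culture cannot be separated from an effect of oxygen on cells with either p53 form.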

How the results depend on the processing

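Most values held under the alternatives. Of 6971 recomputed values of named genes, 6492 stayed the same, 331 were weaker, 32 stronger, 112 moved and 4 reversed. A value that passed stayed the same if it kept its direction and still passed. Where neither value passed, it stayed the same within the SE for a gene or a fixed margin for a list. A larger shift there was counted as moved. Of 1292 recomputed list values, 1227 stayed the same, 24 were weaker, 20 stronger, 21 moved and 0 reversed. Reversed were BBC3 in the hypoxic ratio as the mean over its probes (0.491), NDRG1 in the hypoxic ratio, which had not passed, with the processed signals (−0.154) and the series matrix (−0.154), and LSS in the normoxic ratio as the mean over its probes (−0.028). For BBC3 and LSS the probes of the gene differ, and for NDRG1 the cause was not tested.

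Counts moved most in the difference between conditions. Its 84 calls became 1 with an offset of 0, 0 with the processed signals and 0 with the series matrix, although 1724, 1547 and 1548 genes then had an unadjusted p under 0.05. They became 137 with median centring, 24 without the filter, 148 with the stricter filter and 46 with the separate-channel fit. With the alternatives chosen after seeing the data they were 15 with all local backgrounds as given and 364 with hypoxia arrays 1 and 2 averaged. The normoxic ratio fell from 4233 calls to 2113 with an offset of 0, 1447 with the processed signals and 1446 with the series matrix. The cause was not tested for these.

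Testing every kept probe, which counts probes, gave 13827 calls for the hypoxic ratio, 6724 for the normoxic ratio, 12942 for hypoxia with wild-type p53 and 12503 with mutant p53. Asking also for a 2-fold change left 26, 31, 14, 704 and 606 calls in the order of the report. Leaving out 1 hypoxic replicate gave 5851 to 7220 calls for the hypoxic ratio, 3718 to 4247 for the normoxic ratio, 11 to 167 for the difference, 6622 to 8246 for hypoxia with wild-type p53 and 6482 to 7939 with mutant p53.

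The array paired the 2 RNA samples. With the pairing dropped and the hypoxic channels fitted as unpaired samples, without a block, 6755 genes passed in place of 7955, all of them among the 7955.

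With all local backgrounds as given, the high values on hypoxia array 1 shrank ratios there: BTG2 was 2.27 on that array after the repair and 0.66 as given. The hypoxic ratio then had 5757 calls and the normoxic ratio 2963. Dim genes are the limit of these arrays, since 62.5% to 71.9% of spots were well above background in a channel, and folds of genes at that limit are bounds.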

Other observations

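The gene groups in this part were chosen after their values were seen. Other scalings here are the processed signals, median centring in place of loess, and other scalings between arrays. Host genes of small nucleolar RNAs rose in hypoxia with either p53 form. Of 13, 11 rose and 0 fell with wild-type p53 (median log2 change 1.08, and 1.02 to 1.09 under other scalings). With mutant p53 12 rose and 0 fell (1.01, and 0.97 to 1.02). SNHG12 was at 2.94 with wild-type and 2.82 with mutant p53, GAS5, a host gene linked to growth arrest, at 1.62 and 1.48, SNHG8 at 1.47 and 1.42 and SNHG1 at 1.35 and 1.23, while SNHG10 did not pass (−0.24 and −0.21). Cytosolic aminoacyl-tRNA synthetase genes, many of them targets of ATF4, also rose: of 17, 12 rose and 4 fell with wild-type p53 (median 0.67, and 0.59 to 0.70 under other scalings) and 12 rose and 3 fell with mutant p53 (0.56, and 0.48 to 0.63). AARS1 was at 1.68 and 1.55, WARS1 at 1.33 and 1.74 and GARS1 at 1.22 and 1.16, and HARS1 fell (−0.58 and −0.43).

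Genes named as metallothioneins, a family of metal-binding proteins, fell in hypoxia. Of 7, 6 fell and 0 rose with wild-type p53 (median −0.91, and −0.99 to −0.85 under other scalings) and 6 fell and 0 rose with mutant p53 (−0.86, and −0.95 to −0.85). Whether their probes tell the members of the family apart was not tested. MT1L was at −1.0 and −1.03, MT1E at −0.96 and −1.06 and MT2A at −0.38 and −0.33. In the hypoxic ratio all 7 were lower with wild-type than with mutant p53 (median −0.43), and in the normoxic ratio 6 were lower (median −0.34), where the dye is part of the ratio. Of 36 proteasome subunit genes 26 fell and 0 rose with wild-type p53 (median −0.29, and −0.34 to −0.26 under other scalings) and 26 fell and 1 rose with mutant p53 (−0.32, and −0.38 to −0.28). PSMD12, of the regulatory particle, was at −0.71 with both forms, and PSMB8, an interferon-induced catalytic subunit, fell with wild-type p53 (−0.92) and did not pass with mutant p53 (−0.11, adjusted p = 0.503).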
